A study of Homo sapiens with 4 samples.

How the data were processed

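RNA of MCF7 cells, an established estrogen receptor-positive luminal breast cancer line, was measured on the Affymetrix Human Transcriptome Array 2.0, a 1-colour oligonucleotide array that carries coding and non-coding transcripts. Cells had received a control short hairpin RNA (shControl) or one against BORIS (shBORIS; gene symbol CTCFL) and were kept under puromycin for 7 days. Per the labels' protocols, total RNA was isolated on Qiagen RNeasy columns and copied into biotin-labelled single-stranded cDNA. Each group held 2 arrays. The series calls them biological replicates, and no source used here says whether they came from separate transfections.

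Per the submitters' processing notes the values were made with RMA, and per the series' design text with the Affymetrix transcriptome console. The console's version, the genome build and the probe annotation are not given in the sources used here. The deposited table holds 1 log2 value per feature and array for 70523 features, from about 1.42 to 14.6, with no centring per gene. RMA corrects background, equalises the distribution of probe values between arrays and summarises the probes of a feature, so background correction could not be varied here and no raw intensity, detection call, slide or scan date was used. Equalised distributions also hide any change in the total amount of RNA. The medians of the 4 arrays lay between 4.28 and 4.51, so the values were used as deposited.

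Features were named through GEO's platform annotation of the array. It gave exactly 1 gene symbol for 23781 features, several for 1543 and none for 45199, and 21497 of the first kind matched a current RefSeq gene identifier. Features with several symbols were not named. Biotypes came from RefSeq on assembly GRCh38.p14. Of several features with 1 symbol, which concerned 479 genes, the one with the highest mean over the 4 arrays was kept, which left 22465 genes, 17085 of them protein-coding. TP53, IGF2 and H19 were among the genes without a feature of their own, and the mitochondrially encoded transcripts had none. No genome coordinates are given because the build is not stated.

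Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term, all 4 arrays), with Benjamini-Hochberg adjustment over the 22465 genes and a threshold of 0.05. The fit had 2 residual degrees of freedom and an estimated prior of 3.93. Gene lists (40 fixed from textbook knowledge, 39 with at least 5 measured members, 746 of 893 entries measured) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The list of genes linked to BORIS came from memory of the literature. No list was chosen on these arrays. The design, lists, alternatives and rule for named genes were fixed before the data were examined. The rule named CTCFL, CTCF and 10 fixed genes (PKM, MYC, TERT, BRCA1, NOTCH3, ESR1, TP53, CDKN1A, IGF2, H19), then up to 12 genes per direction past the threshold, filled up to 12 with genes at an unadjusted p under 0.05, a fold of at least 1.5 and no overlap between groups, ranked by log2 fold change, and up to 4 members with the smallest p in each list described. Genes outside the rule are said to be so where they appear.

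The fit was tested on simulated data with 200 of 22465 genes changed in each of 5 draws, with variances drawn from the prior fitted to these arrays. With the spread of all 4 arrays it called 0.597% of genes changed 1.5-fold, 14.3% of those changed 2-fold and 92.7% of those changed 4-fold. With the spread left when shBORIS replicate 2 was set aside, the shares were 91.6%, 100% and 100%. A list of 20 genes shifted by 0.5 was called in 5 of 5 draws. Over the 5 draws, 27 unchanged genes were called with the first spread and 67 with the second. The simulated spreads were independent between genes, which those of real arrays are not. They were also equal on all 4 arrays, whereas shBORIS replicate 2 stood apart, so the shares need not hold for these arrays. As a yardstick for background, chosen after seeing the data, the 358 olfactory receptor genes on the array were used, which breast cells are not expected to transcribe. Their 95th percentile was 4.62 (mean over arrays), and 14697 genes (65.4%) lay above it. The number of arrays limits the precision of every value.

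Alternatives fixed beforehand were quantile normalization, median centring, a filter on dim genes, eBayes with a trend or a robust prior, the replicate number as a block, the mean of a gene's features, each array left out in turn, all features, another adjusted threshold, an unadjusted threshold with a fold minimum, an unmoderated t statistic, camera with an estimated correlation, fry and a rank test. Cyclic loess, array weights, a crossed block and protein-coding genes alone were added after seeing the data. Principal components and figures used R, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.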

Results

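The series asked how the transcriptome of MCF7 breast cancer cells changes when BORIS is depleted. BORIS (CTCFL) is a germ-line paralogue of the chromatin insulator protein CTCF that many tumours express. Transcript levels were measured on 4 arrays, 2 of cells with a control hairpin and 2 of cells with a BORIS hairpin, each after 7 days of puromycin selection. All values are log2 RMA signals, given as mean ± SD with n = 2 per group, and differences are shBORIS minus shControl with the standard error (SE) of the limma fit. Nothing in the labels beyond the series' statement of biological replication says that the arrays came from separate cultures, so p-values measure the spread between these samples.

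Markers of luminal breast cells and of other cell types were set against background, and levels of different probes are not compared with one another. Luminal markers (ESR1, GATA3, FOXA1, keratins 8, 18 and 19 among 17 measured) averaged 8.47 ± 0.01 in shControl and 8.47 ± 0.08 in shBORIS, and all 17 lay above the 95th percentile of 358 olfactory receptor genes (4.62). Fibroblast markers averaged 4.08 ± 0.01 and 4.15 ± 0.22, with 5 of 14 above that level. Endothelial markers averaged 4.65 ± 0.06 and 4.76 ± 0.23 with 7 of 12 above it. Immune cell markers averaged 4.72 ± 0.02 and 4.80 ± 0.24 with 9 of 15 above it. Testis and meiosis genes averaged 3.67 ± 0.01 and 3.72 ± 0.10 with 4 of 23 above it.

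One array stood apart. Over all features the shControl arrays and shBORIS replicate 1 correlated with one another at r = 0.9947 to 0.9950, whereas shBORIS replicate 2 correlated with them at 0.9825 to 0.9886. The first principal component held 81.7% of the variance, with shBORIS replicate 2 at a score of 34.1, shControl replicate 1 at -1.96, shControl replicate 2 at -14.3 and shBORIS replicate 1 at -17.9. In shBORIS replicate 2 the olfactory receptor genes sat 0.18 above the shControl mean (median) and the brightest 2247 genes 0.16 below it; in shBORIS replicate 1 these medians were -0.06 and 0.025. No pair of arrays was a duplicate. The closest pair, shControl replicate 2 and shBORIS replicate 1, differed by an SD of 0.134 over genes, against 0.147 between the shControl arrays and 0.338 between the shBORIS arrays.

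**Figure D1:**
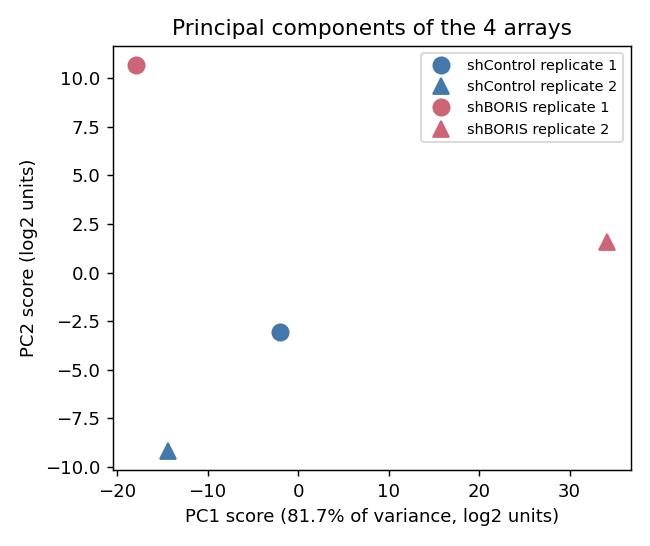
Scores of the 4 arrays on the first and second principal components of 22465 genes (log2 units; colour, group; symbol, replicate). The first component, 81.7% of the variance, sets shBORIS replicate 2 (34.1) apart from the other arrays (-17.9 to -1.96) and does not separate the groups. On the second component the shControl arrays (-3.04 and -9.18) lie below the shBORIS arrays (10.67 and 1.55), which was not tested.

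The targeted gene was examined first. CTCFL, measured by 1 feature, was at 3.96 ± 0.01 in shControl and 3.997 ± 0.24 in shBORIS, with 3.97 and 3.95 on the shControl arrays and 3.83 and 4.17 on the shBORIS arrays. The difference was 0.0375 (SE 0.16, 95% interval -0.35 to 0.42; unadjusted p = 0.82, limma adjusted p = 1), and it was negative (-0.0243) after quantile normalization and (-0.13) without shBORIS replicate 2. The feature's level lay at percentile 89.4 of the olfactory receptor genes and percentile 25.2 of all genes. The signal lay below the olfactory receptor level of 4.62, and whether a fall of CTCFL could be detected there was not tested. No fall shared by both shBORIS arrays was seen, so the targeted transcript does not bear out the shBORIS label and does not contradict it. CTCF, measured well above background, was at 9.01 ± 0.04 and 8.95 ± 0.21 (difference -0.06, SE 0.15, adjusted p = 1 in limma); its sign turned after quantile normalization (0.0204).

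Genes that earlier work ties to BORIS, and the other fixed genes, did not pass the threshold. PKM, a pyruvate kinase gene with alternative exons, was at 10.62 ± 0.02 in shControl and 10.66 ± 0.11 in shBORIS. The PKM difference was 0.0389 (SE 0.13), and -0.0262 after median centring. The gene-level value does not resolve the exons of PKM. MYC was at 8.82 ± 0.01 and 8.74 ± 0.06, a difference of -0.08 (SE 0.12) that was 0.0161 after quantile normalization. TERT, the telomerase subunit, was at 5.99 ± 0.13 and 6.12 ± 0.41. BRCA1 was at 4.95 ± 0.08 and 5.04 ± 0.20, NOTCH3 at 7.82 ± 0.05 and 7.85 ± 0.09 (-0.0341 for the NOTCH3 difference after median centring), the p53 target CDKN1A at 8.02 ± 0.05 and 8.13 ± 0.15, and the estrogen receptor gene ESR1 at 6.55 ± 0.004 and 6.69 ± 0.02 (difference 0.14, SE 0.12). The groups did not overlap for ESR1 and MYC, as chance gives for 33.3% of genes. None of these 9 fixed and targeted genes passed, either over all genes in limma (adjusted p = 1) or adjusted over the list alone (0.82). The 15 measured genes linked to BORIS in earlier literature had a median difference of 0.0389, with 9 higher and 6 lower and none past the threshold (camera adjusted p = 0.93).

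No gene passed the adjusted threshold. The 9 genes that the rule ranked as lower in shBORIS were SPRR1A, ERO1A, CEACAM5, CCL2, TGFB2, CEACAM6, C11orf71, CTBS and SPRR3, all of them protein-coding. SPRR1A, a cornified-envelope precursor, was at 8.20 ± 0.06 in shControl and 7.22 ± 0.16 in shBORIS, a 1.97-fold difference (log2 -0.98, SE 0.14, unadjusted p = 4.61e-04, limma adjusted p = 1). Its relative SPRR3 was at 6.68 ± 0.01 and 6.07 ± 0.10 (log2 -0.61, SE 0.13). Outside the rule and chosen after its value was seen, the relative SPRR1B was at 6.86 ± 0.04 and 6.57 ± 0.30. CEACAM5, which encodes carcinoembryonic antigen, was at 8.60 ± 0.01 and 7.89 ± 0.12 (log2 -0.70, SE 0.13), and CEACAM6 at 7.46 ± 0.04 and 6.78 ± 0.14 (log2 -0.68, SE 0.13). These paralogues have similar sequences, so cross-hybridisation between them was not excluded. CCL2, a monocyte chemoattractant, was at 6.97 ± 0.15 and 6.29 ± 0.08 (log2 -0.68, SE 0.14). TGFB2, a TGF-beta ligand, was at 7.81 ± 0.08 and 7.12 ± 0.18 (log2 -0.68, SE 0.15). ERO1A, an oxidase of the endoplasmic reticulum, was at 10.09 ± 0.08 and 9.36 ± 0.65, CTBS, a lysosomal chitobiase, at 6.53 ± 0.17 and 5.91 ± 0.49, and C11orf71 at 5.52 ± 0.23 and 4.85 ± 0.39; in these 3 genes most of the difference came from shBORIS replicate 2 (ERO1A 9.81 and 8.90 on the shBORIS arrays). Outside the naming rule and chosen after their values were seen, the chemokines CCL5 (9.12 ± 0.001 and 8.55 ± 0.12) and CCL22 (6.54 ± 0.003 and 5.95 ± 0.04) and the cyclin-dependent kinase inhibitor CDKN2B (8.21 ± 0.03 and 7.71 ± 0.07) were separated in the same direction.

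The 8 features that the rule ranked as higher held no protein-coding gene. They were the microRNA genes MIR3200, MIR4644 and MIR4443, the immunoglobulin segment IGHD2-21 and a heavy-chain variable segment, the 5S pseudogene RNA5SP182 and the non-coding genes LOC284009 and FAM215A. Their differences ran from 0.62 (MIR4443) to 0.88 (MIR3200, 4.06 ± 0.03 against 4.94 ± 0.36), and MIR3200, RNA5SP182, MIR4443 and the variable segment lay below the olfactory receptor level of 4.62.

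**Figure D2:**
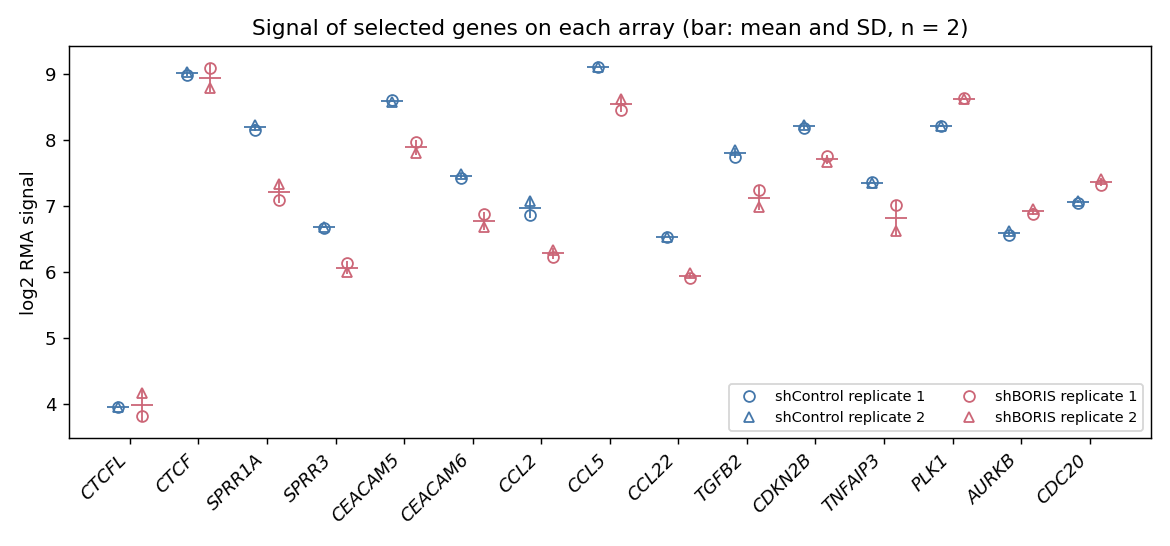
Log2 RMA signal of 15 genes on each array (colour, group; circle, replicate 1; triangle, replicate 2; bar, mean with SD, n = 2). SPRR1A, SPRR3, CEACAM5, CEACAM6 and CCL2 are lower on both shBORIS arrays than on both shControl arrays, whereas CTCFL lies near 4 on all arrays.

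The limma fit called 0 of 22465 genes at an adjusted p of 0.05 (lowest adjusted p = 1), with 151 genes at an unadjusted p under 0.05 (79 higher, 72 lower) where 1123 would be reached by chance. An unmoderated t statistic gave 0 adjusted calls and 438 unadjusted ones. A fold of at least 1.5 at an unadjusted p under 0.05 was reached by 17 genes, 8 higher and 9 lower, and groups did not overlap for 17.5% of genes, against 33.3% by chance. The count rested on single arrays: it was 5 without shBORIS replicate 2 (SPRR1A, IGHD3-16 and OR5V1 lower, SNORD58C and MIR548X higher; unlike SPRR1A, the other 4 fall outside the naming rule) and 5106 without shBORIS replicate 1, each with a lone shBORIS array assumed to vary like the shControl arrays.

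Of the lists fixed beforehand, 2 of cell division genes stood higher in shBORIS than other genes. All 25 measured G2/M and mitosis genes had a positive difference (median 0.15; camera adjusted p = 7.89e-07), but the call was lost with an estimated correlation (adjusted p = 0.91). No member passed, over all genes or over the list alone. PLK1, a mitotic kinase, was at 8.22 ± 0.01 in shControl and 8.63 ± 0.02 in shBORIS (log2 0.42, SE 0.12, unadjusted p = 0.0141, limma adjusted p = 1), AURKB at 6.60 ± 0.03 and 6.93 ± 0.05, CDC20 at 7.07 ± 0.02 and 7.37 ± 0.07, and UBE2C at 6.43 ± 0.07 and 6.66 ± 0.03. Of 24 G1/S and DNA replication genes 21 were higher and 3 lower (median 0.15; camera adjusted p = 3.61e-05; adjusted p = 0.88 with an estimated correlation). Examples are TK1 (7.54 ± 0.03 and 7.84 ± 0.11), TYMS (7.01 ± 0.03 and 7.27 ± 0.12), MCM5 (7.59 ± 0.02 and 7.82 ± 0.01) and ORC1 (5.40 ± 0.04 and 5.66 ± 0.02), none of which passed. The shift lay mainly on 1 array: the G2/M median was 0.37 above the shControl mean in shBORIS replicate 1 and -0.0232 in shBORIS replicate 2, and the G1/S medians were 0.22 and 0.06. Without shBORIS replicate 1 neither list was called (camera adjusted p = 0.22 for G2/M, with its direction turned, and 0.99 for G1/S), and without shControl replicate 1 the G1/S call was lost too (camera adjusted p = 0.12). PLK1, AURKB and CDC20 lay higher on both shBORIS arrays (0.41, 0.36 and 0.35 above the shControl mean in replicate 2).

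NF-kB and inflammatory genes stood lower, 14 of 21 with a negative difference (median -0.10; camera adjusted p = 3.61e-05; adjusted p = 0.88 with an estimated correlation). None passed over all genes or over the list alone (lowest list-alone adjusted p = 0.0592). At an unadjusted p under 0.05 were 5 members, CCL2 (above), TNFAIP3, which ends NF-kB signalling (7.36 ± 0.01 and 6.82 ± 0.28), CCL20 (3.75 ± 0.20 and 3.28 ± 0.10), CXCL8 (4.32 ± 0.15 and 3.91 ± 0.03) and ICAM1 (8.78 ± 0.08 and 8.45 ± 0.08), of which ICAM1 falls outside the rule. CCL20 and CXCL8 lie below the olfactory receptor level. The list's medians were -0.16 in shBORIS replicate 1 and 0.0261 in replicate 2 as deposited, and -0.16 and -0.07 after cyclic loess, and it was not called without replicate 1 (camera adjusted p = 0.0802). Together with the cell division lists it was the only one of the 14 called lists that quantile normalization kept.

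The other 11 called lists had negative medians, and none was called after quantile normalization. With an estimated correlation their adjusted p ran from 0.88 to 0.96, and no member passed. In shBORIS replicate 2 the brightest 2247 genes lay 0.16 below the shControl mean (median), and 5e-04 above it after cyclic loess. On that array cyclic loess raised the medians of cholesterol (-0.1158 to 0.0421) and epithelial junction genes (-0.1351 to 0.0084). Heat shock (-0.2446 to -0.0831) and interferon medians (-0.1998 to -0.0733) also rose. Splicing factors stayed at -0.2083. Cyclic loess lowered hypoxia (-0.0908 to -0.1467) and stemness medians (0.102 to -0.0516). Type I interferon genes had 22 of 27 members lower (median -0.08, camera adjusted p = 0.0018; adjusted p = 0.96 with an estimated correlation), with IFIT2 at 7.53 ± 0.03 and 7.21 ± 0.10 and ISG15 in the other direction at 7.87 ± 0.19 and 8.13 ± 0.16. Hypoxia response genes had 17 of 22 lower (median -0.08, camera adjusted p = 0.0040; 0.88 as the adjusted p with an estimated correlation), with HILPDA at 6.77 ± 0.08 and 6.42 ± 0.22 and CA12 at 8.75 ± 0.09 and 9.04 ± 0.04. Splicing factors had 22 of 26 lower (median -0.12, camera adjusted p = 0.0040; adjusted p = 0.96 with an estimated correlation), with SRSF7 at 6.72 ± 0.11 and 6.45 ± 0.35. TGF-beta target genes had 12 of 18 lower (median -0.09, camera adjusted p = 0.0052; adjusted p = 0.88 with an estimated correlation), led by TGFB2. Stemness genes had 11 of 17 lower (median -0.04, camera adjusted p = 0.0185; adjusted p = 0.88 with an estimated correlation), with ALDH1A3 at 8.45 ± 0.09 and 8.08 ± 0.01 and CD44 at 8.01 ± 0.03 and 7.64 ± 0.24. Heat shock genes (14 of 15 lower, camera adjusted p = 0.0153), immediate early and AP-1 genes (14 of 22, 0.0153), apoptosis regulators (13 of 21, 0.0236, with BCL2A1, below the olfactory receptor level, at 3.98 ± 0.15 and 3.50 ± 0.05), cholesterol synthesis (12 of 18, 0.0367), lysosome and autophagy genes (14 of 21, 0.0375) and epithelial junction genes (12 of 16, 0.0419) complete the set. In that order their adjusted p was 0.96, 0.88, 0.88, 0.96, 0.91 and 0.91 with an estimated correlation. The medians of interferon, splicing, heat shock, stemness, cholesterol and epithelial junction genes had opposite signs on the 2 shBORIS arrays as deposited (splicing factors 0.0648 and -0.28). The interferon, splicing and heat shock lists were called in the opposite direction without shBORIS replicate 2 (camera adjusted p = 0.0107, 1.09e-04 and 9.19e-04). Without that array the hypoxia, TGF-beta, apoptosis, cholesterol, lysosome and epithelial junction lists were not called (camera adjusted p = 0.25 to 0.89), with the direction turned to higher for cholesterol, lysosome and epithelial junction genes, and the stemness and immediate early lists were not called without shBORIS replicate 1 (0.22 and 0.31) or shControl replicate 1 (0.0984 and 0.16). Splicing, heat shock, apoptosis, cholesterol and lysosome genes lost the call without shControl replicate 2, and epithelial junction genes without shControl replicate 1 (camera adjusted p = 0.0603 to 0.30).

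**Figure D3:**
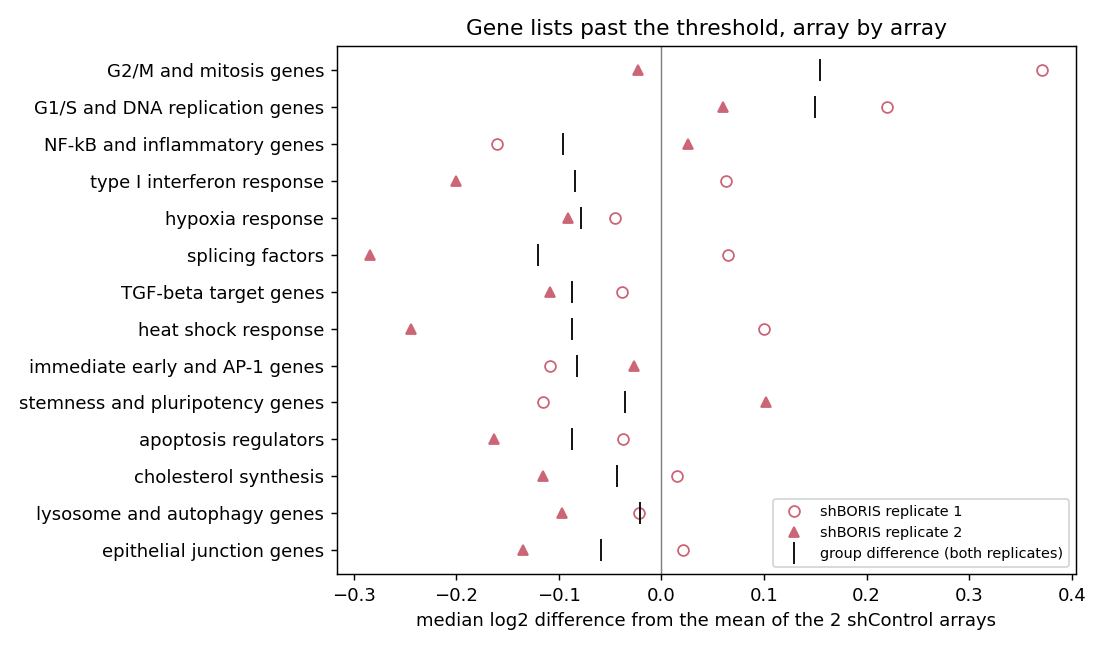
Median log2 difference from the shControl mean for each of the 14 lists called by camera at the preset correlation (open circle, shBORIS replicate 1; triangle, shBORIS replicate 2; bar, median of the group differences). The G2/M list lies at 0.37 in replicate 1 and -0.0232 in replicate 2, and 8 of the 14 lists have medians of opposite sign on the 2 arrays as deposited, against 7 after cyclic loess, where NF-kB and stemness genes no longer do and immediate early genes do.

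The 25 remaining lists were not called (camera adjusted p = 0.0521 to 0.98, medians -0.06 to 0.11). Estrogen response genes had 15 of 28 members higher (median 0.0062, adjusted p = 0.88), with GREB1 at 8.67 ± 0.01 and 8.92 ± 0.03. Luminal markers had a median of -0.0324 (adjusted p = 0.77), with SPDEF at 8.25 ± 0.01 and 8.47 ± 0.03. Glycolysis and lactate export genes had 12 of 21 higher (median 0.0147, adjusted p = 0.98), with PFKL at 7.78 ± 0.001 and 7.91 ± 0.10. Cancer-testis antigens, the class to which CTCFL belongs, had 16 of 18 higher (median 0.10, adjusted p = 0.0633), on -0.09 in shBORIS replicate 1 and 0.27 in replicate 2, and only 9 of the 18 lay above the olfactory receptor level; CT83 was at 7.11 ± 0.22 and 6.77 ± 0.23. Markers of other cell types followed the same array, with endothelial medians of -0.0476 and 0.29 (adjusted p = 0.0521), immune cell medians of -0.08 and 0.29 (0.15) and fibroblast medians of -0.08 and 0.19 (0.32) in shBORIS replicates 1 and 2. In shBORIS replicate 2 the olfactory receptor genes also lay 0.18 above the shControl mean (median). Cancer-testis antigens were not called after quantile normalization or cyclic loess (camera adjusted p = 0.29 and 0.30). Endothelial markers were called higher in 5 other settings (array weights, protein-coding genes alone, the rank test, and without shBORIS or shControl replicate 1). Cancer-testis antigens were called higher in 3 (protein-coding genes alone, the rank test and without shBORIS replicate 1). Oxidative stress genes were called lower in 3 (array weights, the rank test and without shBORIS replicate 1). CTCF, cohesin and loop factors (0.27), DNA methylation machinery (0.92), imprinted genes (0.98), testis and meiosis genes (0.32) and p53 targets (0.25) also missed the camera threshold. Single arrays decided the loop factor, p53 and small nucleolar RNA lists, which were called lower without shBORIS replicate 1 and higher without shBORIS replicate 2. Their medians were 0.1083, 0.0367 and 0.1602 in shBORIS replicate 1 and -0.2652, -0.0964 and -0.1431 in replicate 2. Without shBORIS replicate 2, 13 lists outside the 14 were called, and without shBORIS replicate 1, 8 were. The threshold was also missed by oxidative stress (0.0557), antigen presentation (0.14), DNA repair (0.25), unfolded protein and ATF4 response (0.29), mesenchymal genes (0.45), small nucleolar RNAs (0.58), TCA cycle and respiratory chain (0.58), basal markers (0.58), MYC targets (0.66), cytosolic ribosomal proteins (0.93), fatty acid synthesis (0.93) and replication-dependent histones (0.93), each value being the list's adjusted p.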

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

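Cyclic loess, array weights, the crossed block and protein-coding genes alone were chosen after seeing the data. The limma count of 0 genes held under quantile normalization, median centring, the filter on dim genes, a trend or robust prior, the mean of features, cyclic loess, array weights, protein-coding genes alone, all features, an adjusted threshold of 0.1 and an unmoderated t statistic. It was 17 at an unadjusted p under 0.05 with a fold of at least 1.5, and ran from 0 to 5106 with single arrays left out, the highest without shBORIS replicate 1. Such fits assume that a lone array varies like the other group. Array weights cannot single out an array here, since both arrays of a group of 2 deviate equally. Same-numbered arrays deviated with r = -0.502 over genes, and the labels do not say that a number marks a shared day or batch. With the replicate block 0 genes passed (170 at an unadjusted p under 0.05) and 11 lists were called. With the crossed pairing 20 genes passed and 11 lists were called. Under either block the immediate early, lysosome and epithelial junction lists lost the call (camera adjusted p = 0.0570, 0.0590 and 0.0630).

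Against 14 lists, 3 were called under quantile normalization and 8 under median centring, all among the 14, 5 under the filter on dim genes and 5 under cyclic loess, 4 of them among the 14 in each case, 0 with an estimated correlation and 0 with fry; the cause was not tested. With single arrays left out 10 to 21 lists were called, of which 5 to 10 were among the 14 in the same direction. The CTCFL difference reversed to -0.0243 under quantile normalization, -0.0277 under median centring and -0.0282 under cyclic loess, ran from -0.1325 to 0.2074 with single arrays left out, and has no value under the filter on dim genes. CTCF reversed to 0.0204 and MYC to 0.0161 under quantile normalization, PKM to -0.0262 and NOTCH3 to -0.0341 under median centring, CTCF to 0.0036 under cyclic loess, and OR5V1 to 0.0807 with the mean of its features. With single arrays left out CTCF ran from -0.2139 to 0.0853, PKM from -0.0397 to 0.1174, TERT from -0.1558 to 0.4192, BRCA1 from -0.0552 to 0.227, NOTCH3 from -0.0331 to 0.0951, CDKN1A from -0.005 to 0.2062, TOP2A from -0.0641 to 0.6504 and KIF11 from -0.2663 to 0.675 (mitotic genes outside the naming rule, chosen after their values were seen), IGHD3-16 from -1.3391 to 0.0547, OR5V1 from -1.1238 to 0.4803, SNORD58C from -0.7787 to 0.9766 and MIR548X from -1.8578 to 0.9211; the cause was not tested. Over single genes, 1012 other values kept direction and side of the threshold, and 67 passed it in the same direction. The passes came only from fits with a lone shBORIS array or with the crossed block, which was chosen after seeing the data. As no gene passed in the main fit, keeping the side of the threshold means only not passing. The direction could not change under a trend or robust prior, either block, array weights, the dim-gene filter or protein-coding genes alone. Signal near background limits CTCFL, and the number of arrays limits every result.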

Other observations

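All tests below except that of signal compression were chosen after the results, or values that foretell them, were seen. Among 12527 expressed protein-coding genes, 17 had both shBORIS arrays below both shControl arrays by at least 0.3, and 3 above. Beside genes already described, the lower ones were CLDN1, a tight junction protein, CYP1B1, ERRFI1, a feedback inhibitor of EGFR signalling, HLA-DRB4, S100A9 and TFPI2. The 3 higher ones were PLK1, FOXM1, a transcription factor of mitotic genes (difference 0.39), and TMEM88 (0.37). These genes were picked by their values, and none passed in limma.

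shBORIS replicate 2 also differed by class of RNA: medians against the shControl mean were -0.61 for 42 MIR548 genes, -0.41 for 73 RNU6 genes and 0.37 for 191 immunoglobulin and T cell receptor segments, against 0.23, 0.0448 and -0.0564 in replicate 1. Compression of the signal alone is argued against, since its SD over genes stayed 2.03 times that of replicate 1 after cyclic loess (2.19 before). An effect of the hairpin shared by both arrays is argued against as the source of this distance. On the first principal component the shBORIS arrays lay on opposite sides of both shControl arrays (-17.9 in replicate 1 and 34.1 in replicate 2). Differences with no array in common correlated over genes at -0.4782 and -0.031, which largely restates those scores. A smaller shared effect is not excluded. Lower recovery of small RNAs stays open as a part, with small nucleolar RNA genes at -0.127 relative to protein-coding genes of matched level, against 0.0901 in replicate 1. A source of variation that the shControl arrays share, such as RNA quality or culture state, may also contribute, since half-differences within the groups correlated at -0.502, but no batch is given.

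Of the 9 genes named as lower, among them SPRR, CEACAM and chemokine genes, 7 stayed below -0.3 without shBORIS replicate 2, but they were picked as lower on both shBORIS arrays, which largely fixes that count. Without shBORIS replicate 2, SPRR1A was at -1.0938, CCL2 at -0.74 and CEACAM5 at -0.62. These values rest on 1 shBORIS array. On it IGHD3-16 and OR5V1, outside the naming rule, were at least as low (-1.3391 and -1.1238). In shBORIS replicate 2 SPRR1A was at -0.8607 against the shControl mean, and IGHD3-16 and OR5V1 at 0.0547 and 0.4803. The part of the stray array therefore stays open for SPRR1A as for the others. Selection by chance cannot be told apart from a shared effect. The 50 genes lowest in 1 pair of arrays had a median of 0.1137 in the other pair (22 of 50 lower). Random draws ran from -0.2409 to 0.1576. With the pairs crossed the median was -0.2488 (37 of 50 lower, below the lowest draw, -0.1315). The 50 highest genes had medians of -0.3154 (2 of 50 higher), and -0.0282 with the pairs crossed (24 of 50 higher). A selection with no hairpin contrast gave a larger value. The 50 genes lowest in shControl replicate 1 minus shControl replicate 2 had a median of -0.5146 in shBORIS replicate 2 minus replicate 1. Of these, 45 of 50 were lower, and the lowest draw was -0.2531. The value is 0.5146 in shBORIS replicate 1 minus replicate 2. It largely restates the negative correlation of the differences within the groups (-0.4822 after cyclic loess), so it is no separate evidence against a shared effect. Of the 3 splits of the arrays, 2 gave at least 17 genes on 1 side by this gap, the real one 17 and the highest other 68, and 3 splits are too few for a share under 0.05. The split of shControl replicate 1 and shBORIS replicate 2 against the others gave 3270 genes at an unadjusted p under 0.05, against 151 in the real one, which points to a structure of the arrays other than the groups.

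The G2/M list was shifted on 1 array: after cyclic loess its median lay at percentile 100 of random lists of matched level in shBORIS replicate 1 and at percentile 11.34 in replicate 2. The second value gave no sign of the shift in replicate 2. It cannot decide whether the hairpin shifted the list in both arrays, because replicate 2 stood apart. Random lists also lack the correlation between G2/M genes. PLK1, AURKB, CDC20 and FOXM1 were higher on both arrays, but they were picked by their values. KIF11 and TOP2A, also chosen after their values were seen, were at -0.2663 and -0.0641 in replicate 2 against the shControl mean. A difference in growth state of shBORIS replicate 1 may account for the list's shift, and no test separated a biological from a technical source for that single array.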
